A study of Mus musculus with 22 samples.

How the data were processed

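RNA from mouse embryonic fibroblasts (MEFs, primary cells grown from whole embryos) was measured on Affymetrix whole-genome mouse expression arrays, on which each probe set is a group of probes designed against a transcript. The cells had been infected with an adenovirus that carried either GFP or Cre recombinase, and RNA was taken 7 days later. Per the labels, Cre switched on a mutant oncogene, which is not reported here by name,, deleted the gene of the transcription factor Wt1, or did both, depending on the alleles of the cells. The 22 arrays fell into 5 control arrays given the GFP virus, 5 oncogene arrays, 5 Wt1-null arrays and 7 double arrays with both changes. The series' design text names 6 oncogene arrays, of which 5 were used here. Replicate numbers were those of the labels, which give 1, 3, 4, 5 and 6 for the oncogene arrays.

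The authors deposited log2 values, normalized with Affymetrix Expression Console by RMA, per the submitters' processing notes and the series' design text. RMA subtracts background, sets all arrays to a common distribution and summarises the probes of each probe set. It compresses differences near the floor, and it would hide a change shared by most transcripts. The software version was not given in the sources used here. The values ran from 3.29 to 15.14, and the array medians from 6.23 to 6.33. No detection calls, scan dates or scanner files were used here, and the number of arrays limits the precision. The labels do not say whether replicates came from separate embryos or cultures, so p-values measure the spread between these arrays, part of which may be technical.

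The table held 45101 probe sets, of which 64 were controls. A platform annotation named 1 gene for 34945 probe sets and several for 932, and 9160 had no gene listed in it. Of the probe sets with 1 gene, 34741 matched the RefSeq gene table of mouse assembly GRCm38.p6 by gene ID, and 0 symbols changed. Each of 18193 genes was represented by its probe set with the highest mean over all arrays. No genome build belongs to the array values, so no coordinates are given.

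Group means were fitted with limma version 3.58.1 in R version 4.3.3 (lmFit and eBayes, all 22 arrays, 4 group means), and p-values were adjusted by the Benjamini-Hochberg method over genes. A gene was called at an adjusted p below 0.05. The comparisons were oncogene against control, Wt1-null against control, double against oncogene, double against Wt1-null, and the interaction, which is the oncogene effect in Wt1-null cells minus that in cells with Wt1. Every oncogene, Wt1-null and double array received Cre and every control array received GFP, so a comparison with the control also compares the viruses, and the interaction, which contains the control, includes the change of virus. The double against oncogene and double against Wt1-null comparisons are between groups that all received Cre.

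Before the data were examined 25 gene lists were fixed, covering growth signalling, cell cycle, stress responses, matrix, metabolism and markers of other cell types. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 25 lists within each comparison. An estimated correlation and fry were planned beside it, and an exact two-sided permutation test of each list's mean per array was added after seeing the data. The genes named were fixed by a rule written beforehand. Per comparison of groups it took the 8 largest rises and the 8 largest falls among called genes whose arrays did not overlap, leaving out clone names, and up to 4 called members of each list with the smallest p. For the interaction it took up to 5 genes per sign, and it always included Wt1 itself. Genes named outside this rule are said to be so.

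The alternatives planned before the data were examined were the mean of all probe sets of a gene, every probe set, a filter on dim genes, repeated quantile normalization, median centring, a trended and robust variance, array weights, a fit of only the groups compared and an added limit of 1 on the log2 change. The replicate number as a block, the set of accessions as a fixed or random block, and leaving out each array in turn were also planned. The accession numbers fell into 3 sets, treated as possible batches. Leaving out arrays that stood apart, averaging a near-identical pair, an Xist covariate, fits within 1 accession set and the naming rule without Wt1-null replicate 2 were added after seeing the data.

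The fit was tested on simulated data with the real gene means and spreads and 200 changed genes among 18193. A log2 change of 1 was recovered for 80% of 50 changed genes in oncogene against control, 76% in Wt1-null against control, 74% in double against oncogene, 78% in double against Wt1-null and 54% in the interaction. The simulated noise was independent between genes, which the real arrays were not.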

Results

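Gene expression was compared in MEFs 7 days after adenoviral infection, in 5 control arrays given GFP virus and in 5 oncogene, 5 Wt1-null and 7 double arrays given Cre virus. The design asks how a mutant oncogene and loss of Wt1, a zinc finger transcription factor of kidney, gonad and mesothelium, change the transcriptome alone and together. All levels are RMA values on the log2 scale, and changes are log2 differences between group means with the standard error (SE) of the limma fit.

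Wt1 gave no check of the labels. The probe set for Wt1 read 4.38 ± 0.10 (SD, n = 5) in control, 4.59 ± 0.07 (SD, n = 5) in oncogene, 4.47 ± 0.16 (SD, n = 5) in Wt1-null and 4.45 ± 0.19 (SD, n = 7) in double arrays. Those levels lay at the 14.1th percentile of all probe sets, within the range of 3.65 to 5.06 that 3 Y-linked genes gave in the 9 arrays with high Xist, the RNA of the inactive X chromosome. A deletion of Wt1 could not be seen at that level. Xist was high in 2 of 5 control, 0 of 5 oncogene, 2 of 5 Wt1-null and 5 of 7 double arrays, a difference between oncogene and double arrays with p = 0.0278 in a two-sided Fisher's exact test.

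Several arrays did not sit with their group. The array closest to Wt1-null replicate 1 was control replicate 2, with a correlation of 0.990. Wt1-null replicate 2 was closest to double replicate 2, with a correlation of 0.998 over all probe sets and an SD of their difference of 0.152, against 0.285 for the next pair of arrays from different groups. Wt1-null replicates 3 and 4 were also nearly alike, with an SD of 0.162 against 0.242 for the next pair within a group. Their probe set for 18S ribosomal RNA read 11.55 and 8.76, and they were kept as 2 arrays. They may be technical replicates, which would leave 4 Wt1-null samples in place of 5. With their average in place of both, 3 genes were called in Wt1-null against control (0 higher, 3 lower), 0 in double against Wt1-null and 0 in the interaction by limma, against 19, 15 and 2 with both kept. Oncogene replicate 4 and double replicate 4 had the lowest mean correlations with all other arrays, 0.963 and 0.940. They also had the largest excess of 3' over 5' signal for pyruvate carboxylase, 2.73 and 2.97 log2 units. For actin this excess was 0.33 and 0.28, below the 0.57 of double replicate 3, and for Gapdh 0.11 and 0.12, below the 0.21 of double replicate 2, so the 3 transcripts gave no common sign of shorter RNA.

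Oncogene MEFs against control MEFs had the most called genes among the 5 comparisons of the design when all 22 arrays were kept and weighted alike, but not without Wt1-null replicate 2 (486, against 925 for double against Wt1-null). Nrcam, a neuronal cell adhesion molecule, rose by 4.87 ± 0.60 (SE), and the urea transporter Slc14a1 by 4.80 ± 0.94. The control means of Nrcam and Esm1, 4.92 and 4.75, lay within the background range of the Y-linked genes, so the sizes and ranks of their rises are not exact. Other probe sets above background gave 2.15 (called) and 0.34 for Nrcam and 0.40 for Dlk1. Esm1, a secreted proteoglycan, the angiotensin receptor Agtr2 and the growth factor Bmp2 rose by 4.78, 4.17 and 4.03. Dlk1, Cd34 and the complement inhibitor Serping1 rose by 3.87, 3.37 and 3.35. The largest falls were in Trib3, a pseudokinase of the amino acid and endoplasmic reticulum stress response, which changed by -3.74 ± 0.39, and Chac1, an enzyme that degrades glutathione, at -2.65 ± 0.37. Keratin 7 (Krt7), the mitochondrial folate enzyme Aldh1l2, Cdsn, the secreted carbonic anhydrase Car6, the extracellular superoxide dismutase Sod3 and Fbxo17 changed by -2.64, -2.53, -2.45, -2.37, -2.15 and -1.86.

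**Figure D1:**
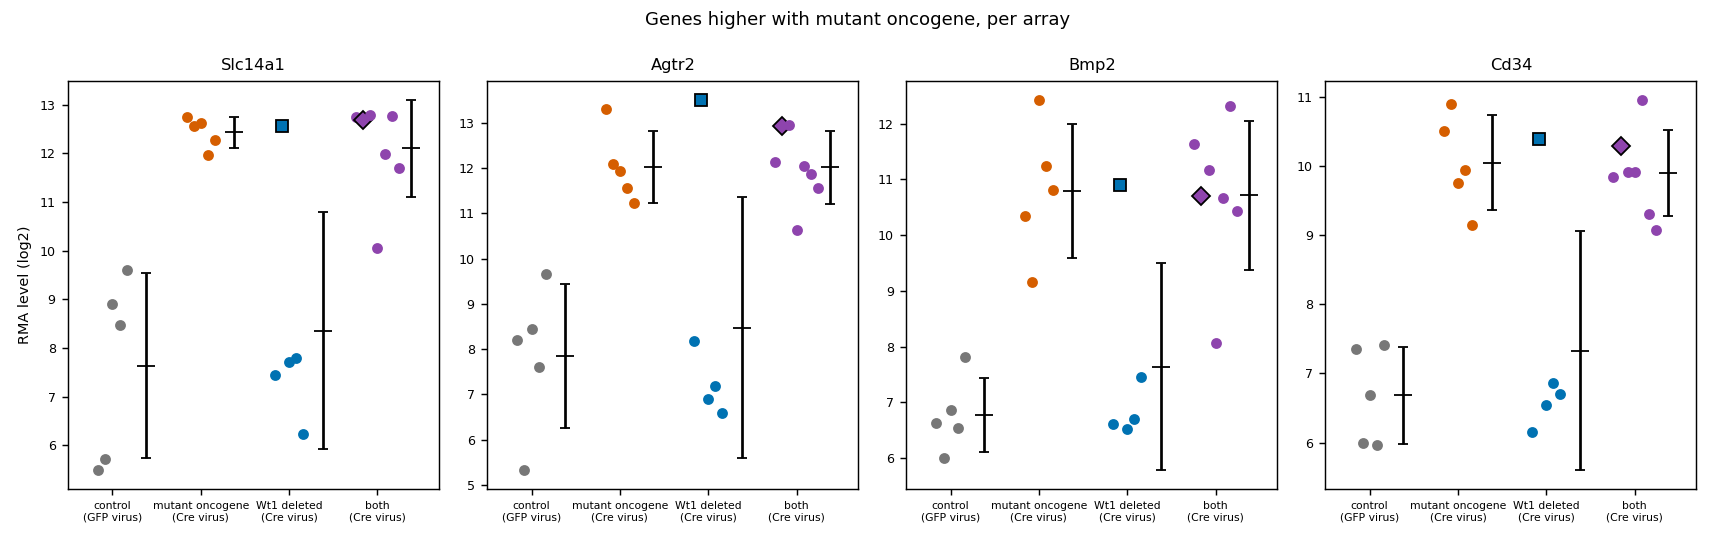
RMA level (log2) of Slc14a1, Agtr2, Bmp2 and Cd34 in each array, by group, with the mean and SD beside the points. The square marks Wt1-null replicate 2 and the diamond double replicate 2, and Slc14a1 read 12.57 in the first of these against 6.24 to 7.79 in the other Wt1-null arrays.

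Genes driven by mitogen-activated protein kinase (MAPK) signalling rose together in oncogene MEFs. All 20 measured members were above the control, with a median change of 1.05, and 8 were called, or 15 when adjusted over the list alone. The camera adjusted p was 2.74e-19, and 0.00497 with an estimated correlation. The Sprouty feedback inhibitors Spry2 and Spry4 rose by 1.43 and 1.31, the transcription factor Etv5 by 1.61 and the chromatin protein Hmga2 by 1.18. Other probe sets gave 0.14 for Spry2, 0.43 to 2.25 for Spry4 and 0.62 and 1.45 for Etv5, so the sizes depend on the probe set. Genes of the unfolded protein response fell, with 17 of 21 below the control, 6 called and 12 called when adjusted over the list alone (median -0.70, camera adjusted p = 2.47e-09, and 0.00535 with an estimated correlation). Among them Ddit3, a transcription factor of stress-induced cell death, changed by -1.56 and Herpud1, which serves protein disposal at the endoplasmic reticulum, by -1.23.

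Genes of cholesterol synthesis lay below the control in oncogene MEFs at all 16 members, with 1 called and 10 called when adjusted over the list alone (median -0.71, camera adjusted p = 7.84e-08, and adjusted p = 0.31 with an estimated correlation). The called member was Lss, lanosterol synthase, which fell by 1.25, and 2 other probe sets of Lss gave -0.26 and -0.14 with no call. The interferon response list (median 0.36), the DNA replication list (median 0.20) and the contractile fibroblast list (median -0.30) passed with the preset correlation, and each had an adjusted p = 0.667 with an estimated correlation. With the replicate block the median of the DNA replication list was -0.084 and it did not pass. Single called members of other lists were Mmp3, a matrix protease, higher by 3.09, the immediate early factor Egr3 by 2.89, Igf1r by 1.34, Col6a3 by 1.18, Igfbp6 by 0.73 and E2f2 by 0.45. For Egr3 and E2f2 another probe set gave -0.101 and -0.062, so these rises rest on 1 probe set each, and the control mean of E2f2, 4.80, was at background. For Igf1r 4 other probe sets gave 0.08 to 0.69 with no call. Gsr and Slc7a11, both of glutathione metabolism, changed by -1.07 and -0.76. The other 19 lists, among them the CDK inhibitors, p53 targets, mitosis, glycolysis, HOX genes and all markers of other cell types, did not pass.

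In total 371 of 18193 genes were called between oncogene and control arrays, 240 higher and 131 lower, and 201 of them differed by at least 1. The excess of rises was not stable, with 331 higher and 327 lower without oncogene replicate 4 and double replicate 4, and 1982 higher and 2435 lower with array weights. Over all genes tested, the arrays of both groups did not overlap for 1081, against 144.4 by chance (0.794%), a reference that takes no account of correlation between genes. The count was 145, 139 and 166 without control replicates 2, 3 and 4, and 223, 177 and 213 without oncogene replicates 3, 5 and 6. It was 617 and 683 without double replicates 1 and 4, 770 in a fit of both groups alone, 4417 with array weights, 658 without oncogene replicate 4 and double replicate 4, and 309 within the accession set that held 4 arrays of each group.

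The largest falls called in Wt1-null MEFs against control MEFs were in genes that were also low in oncogene MEFs. Trib3 changed by -3.22 ± 0.39 (SE), Chac1 by -2.32, Aldh1l2 by -2.27 and Car6 by -2.17 ± 0.23. Wt1-null replicate 1 lay nearest the controls, with Trib3 at 9.56 against 6.68 to 7.52 in the other Wt1-null arrays and a control mean of 10.83. The mitochondrial enzyme Pck2, the neurotrophic factor Artn, the thioesterase Acot2 and the glycine transporter Slc6a9 changed by -1.93, -1.65, -1.59 and -1.26. Nudt6 rose by 2.27, Errfi1, a feedback inhibitor of the EGF receptor, by 1.57, Phlda1 by 1.38, the nucleotide sugar transporter Slc35d1 by 1.35, the nuclear pore protein Pom121 by 1.30 and the receptor Epha2 by 0.93. Other probe sets of Nudt6, Slc35d1, Pom121, Acot2 and Slc6a9 gave 0.08, 0.37, 0.74, -0.34 and -0.36 with no call, so the sizes of these changes rest on 1 probe set each. No named gene is a check of Wt1 loss, and of the 23 measured genes on the list of reported WT1 targets none was called.

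**Figure D2:**
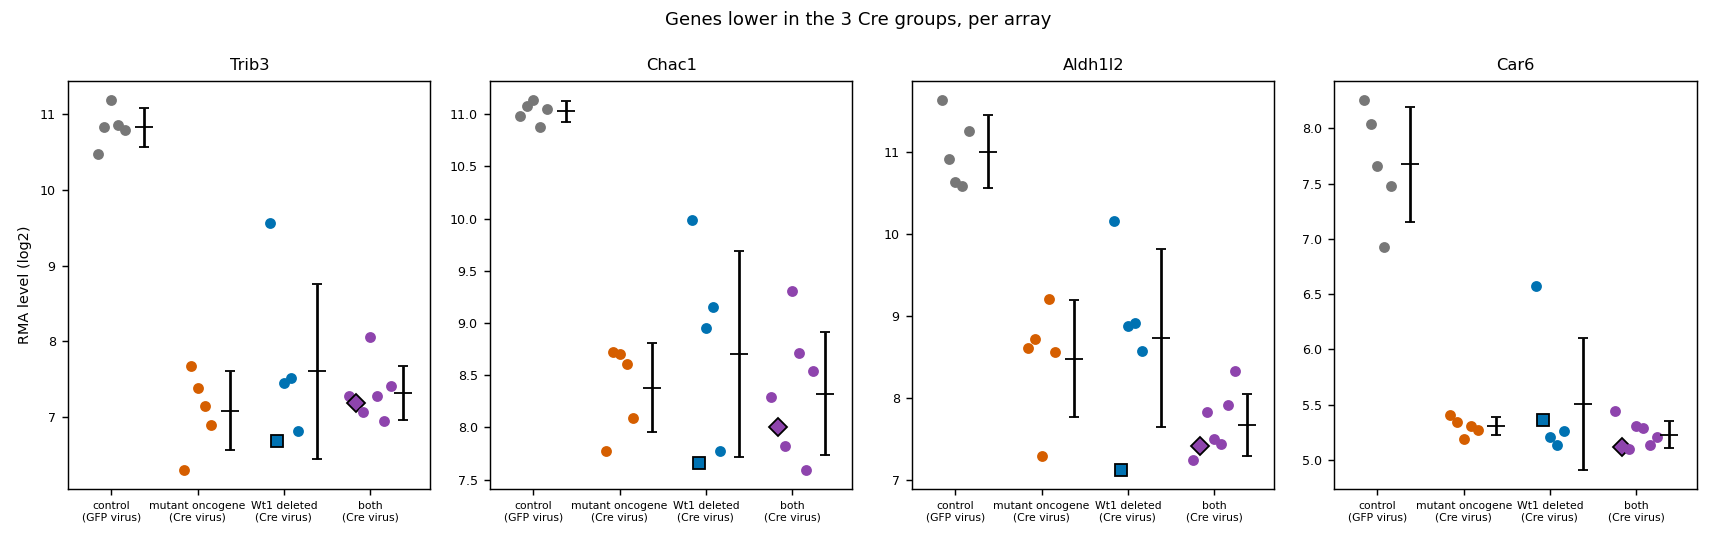
RMA level (log2) of Trib3, Chac1, Aldh1l2 and Car6 in each array, by group, with the mean and SD beside the points. Square and diamond mark Wt1-null replicate 2 and double replicate 2, and for Trib3 the control mean was 10.83 against 7.08, 7.61 and 7.32 in the oncogene, Wt1-null and double groups.

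The MAPK output list also rose in Wt1-null MEFs, with all 20 members above the control, 2 called (Phlda1 and Epha2) and 12 called when adjusted over the list alone. Its median change was 0.81 (camera adjusted p = 1.82e-16, and 0.0109 with an estimated correlation). Without Wt1-null replicate 2 the median was 0.70, 18 of 20 members were higher, and the adjusted p was 0.0276 with an estimated correlation. The unfolded protein response list had 15 of 21 members lower, 2 called and 10 when adjusted over the list alone (median -0.44, camera adjusted p = 2.35e-05, and adjusted p = 0.0591 with an estimated correlation). Other lists that passed with the preset correlation were reported WT1 targets (median 0.19), secreted factors of senescence (0.36), immediate early genes (0.36), contractile fibroblast genes (0.29), p53 targets (0.17), fibrillar matrix (0.07) and NRF2 targets (-0.32). With an estimated correlation their adjusted p-values lay between 0.267 and 0.885. Without Wt1-null replicate 2, p53 targets had a median of -0.046 with 10 of 20 members higher and did not pass (adjusted p = 0.868 with camera). Contractile fibroblast genes then had a median of 0.50 and senescence factors 0.22, and the mitosis list was higher at 26 of 27 members (median 0.34, camera adjusted p = 0.00023, and adjusted p = 0.797 with an estimated correlation). The other 16 lists did not pass.

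Of the 18193 genes, 19 were called between Wt1-null and control arrays, 6 higher and 13 lower, and 2311 had an unadjusted p below the threshold. The arrays of both groups did not overlap for 1034 genes, against 144.4 by chance (0.794%). With median-centred arrays the split was 6 higher and 7 lower. The count was 41, 3, 3 and 11 without Wt1-null replicates 1, 3, 4 and 5, and 8, 9, 2, 2 and 2 without control replicates 1 to 5 in turn. It was 121, 42, 12 and 12 without double replicates 1, 4, 5 and 7, and 12 without oncogene replicate 3, 5 or 6. Other values were 599 in a fit of both groups alone, 6016 with array weights, 79 without oncogene replicate 4 and double replicate 4, 3 with accession set as a fixed block, 5 as a random block, and 0 within the set of 3 Wt1-null and 1 control array.

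Both comparisons used the same control arrays, and their calls overlapped. All 13 genes lower and 4 of 6 genes higher in Wt1-null MEFs were called in the same direction in oncogene MEFs. Independent lists would share 0.0936 lower and 0.0792 higher genes. When the residuals of the arrays were dealt at random to unchanged groups, a mean of 0 calls was shared over 100 draws. These draws had a mean of 0.01 calls in oncogene MEFs, so they do not measure how far the common controls raised the overlap. With the controls split into parts of 2 and 3 arrays, a median of 2 genes was called in Wt1-null MEFs and a median of 2 calls was shared. The correlation of the changes was 0.658, against a mean of 0.456 and a highest of 0.913 for unchanged groups and a median of 0.529 with split controls. The covariance of the changes across genes was 0.0839, against a mean of 0.0279 for unchanged groups, whose highest value was 0.0898.

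Double MEFs against oncogene MEFs, the effect of Wt1 deletion where the mutant oncogene was active, gave no called gene. The 27 measured genes of mitosis were all lower in the double group (median -0.90), as were all 28 genes of DNA replication (median -0.57). No member of either list was called, over all genes or when adjusted over the list alone. The mitosis list averaged 9.69 ± 0.67 (SD, n = 7) in double and 10.57 ± 0.54 (SD, n = 5) in oncogene arrays, a difference of -0.88 with an exact permutation p = 0.0391, or 0.489 adjusted over the 25 lists. With camera the adjusted p-values were 1.80e-28 for mitosis and 1.06e-18 for DNA replication, and adjusted p = 0.136 and adjusted p = 0.255 with an estimated correlation.

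Cholesterol synthesis genes (16 of 16 lower, median -0.19), fibrillar matrix (-0.18), contractile fibroblast genes (-0.18), p53 targets (0.23), epithelial markers (0.14) and sex-linked genes (-2.36) also passed with the preset correlation in double against oncogene arrays. Their adjusted p-values with an estimated correlation lay between 0.136 and 0.599. With Xist as a covariate the contractile fibroblast list turned to 0.081 and did not pass. The sex-linked genes moved with the 5 of 7 double arrays and 0 of 5 oncogene arrays that were high in Xist. The other 17 lists did not pass. The arrays of both groups did not overlap for 16 genes, against 45.9 by chance (0.253%). With limma, 0 genes were called and 562 had an unadjusted p below the threshold, and 0 were called under each alternative run, including every left-out array and the set of accessions with 7 double and 4 oncogene arrays.

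Double MEFs against Wt1-null MEFs, the effect of the mutant oncogene where Wt1 was deleted and all cells had received Cre, depended on Wt1-null replicate 2. With all arrays, Ezh1, a histone methyltransferase, rose by 0.98 ± 0.19 (SE), Gsap by 0.86 ± 0.12, Hsd17b11 by 0.66 and Tcf24 by 0.45 (from a Wt1-null mean of 4.64, at background), while Rasal2, a GTPase-activating protein, fell by 1.03 ± 0.18. Other probe sets above background gave 0.11 for Ezh1, 0.42 for Gsap, 0.04 for Hsd17b11 and -1.02 for Rasal2, with no call. The contractile fibroblast genes were lower at all 16 members (median -0.88), with 0 called and 13 called when adjusted over the list alone. Cholesterol synthesis genes were lower at all 16 members (median -0.75), with 11 called when adjusted over the list alone. The camera adjusted p-values were 2.60e-16 and 1.67e-12, and adjusted p = 0.124 for both with an estimated correlation.

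Interferon response genes were higher at 25 of 25 members (median 0.34) and mitosis genes lower at 27 of 27 (median -0.85) in double against Wt1-null arrays, with preset correlation adjusted p-values of 7.47e-05 and 2.07e-14. With an estimated correlation these were adjusted p = 0.519 and adjusted p = 0.388. MAPK output (0.29), DNA replication (-0.30), fibrillar matrix (-0.24), the unfolded protein response (-0.28) and chondrocyte markers (-0.16) passed only with the preset correlation, with adjusted p-values of 0.173 to 0.61 otherwise. The other 16 lists did not pass.

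Leaving out Wt1-null replicate 2 was planned along with every other array, and the naming rule was applied to this setting after its values were seen. The genes higher in double than in Wt1-null MEFs then included several of the genes highest in oncogene MEFs. Slc14a1 was higher by 4.80 ± 0.67 (SE), Agtr2 by 4.80 ± 0.60, Bmp2 by 3.88, Nptx1 by 3.88, Scara5 by 3.57, Cd34 by 3.33, Mmp3 by 3.27 and the Wnt antagonist Frzb by 3.07. The gap junction gene Gjb2 changed by -4.35, the myosin Myh1 by -4.01, C1qtnf3 by -3.52, calponin 1 (Cnn1) by -3.32, Krt7 by -3.11, Limch1 by -2.88, Rgs4 by -2.77 and Mgll by -2.76. The Wt1-null mean of Nptx1, 4.97, and the double mean of Myh1, 4.87, were at background, so the sizes and ranks of these changes are not exact. Of the 16 contractile fibroblast genes 12 were called, all lower, with Cnn1, Myh11, Lmod1 and Tagln at -3.32, -1.90, -1.65 and -1.14 (adjusted p = 0.0594 with an estimated correlation). Of the mitosis list 7 genes were called lower, and 26 of 27 when adjusted over the list alone, among them Tpx2 at -1.29 and Aurka at -1.17 (adjusted p = 0.2 with an estimated correlation). Of the MAPK output list 5 genes were called higher, with Etv5 at 1.77, Dusp6 at 1.72, Spry4 at 1.32 and Spry2 at 0.92 (adjusted p = 0.415 with an estimated correlation).

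With all arrays 15 genes were called between double and Wt1-null arrays, 10 higher and 5 lower, and 925 without Wt1-null replicate 2, 589 higher and 336 lower. With median-centred arrays 5 were higher and 4 lower. With all arrays both groups did not overlap for 168 genes, against 45.9 by chance (0.253%). Of the 925 genes, 128 were called between oncogene and control arrays, which are other arrays, and 128 of them had the same direction, against 10.2 for independent lists. The count was 0 without Wt1-null replicate 1, 3 or 4 or double replicate 3 or 5, and 1 without Wt1-null replicate 5, control replicate 2, 3 or 4, oncogene replicate 6 or double replicate 1 or 6. It was 2 without oncogene replicate 5 or double replicate 4, 3 without double replicate 7 and 57 without oncogene replicate 4. No accession set held both groups, and 0 genes were called with the set as a fixed or random block, in a fit of both groups alone, or with Wt1-null replicates 3 and 4 averaged.

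The interaction was called at 2 genes, Trib3 (3.46 ± 0.53, SE) and Car6 (2.09 ± 0.32), each with an adjusted p of 0.0167. Both were low in all 3 groups given Cre virus, so that the fall in double MEFs was smaller than the sum of the falls in oncogene and Wt1-null MEFs. That sum would have taken Trib3 into the background range of 3.65 to 5.06 and Car6 below it. An additive fall could therefore hardly have been seen at either gene. The MAPK output list had a negative interaction at all 20 members (median -0.71, camera adjusted p = 2.69e-10, and adjusted p = 0.0917 with an estimated correlation). Mitosis (27 of 27 negative, median -0.93), DNA replication (-0.57), contractile fibroblast genes (-0.50), immediate early genes (-0.64), fibrillar matrix (-0.24), secreted factors of senescence (-0.20) and reported WT1 targets (-0.08) were negative. NRF2 targets (0.39) and the unfolded protein response (0.20) were positive. These 9 passed with the preset correlation and had adjusted p-values of 0.386 to 0.415 with an estimated one. With accession set as a fixed block the secreted factors of senescence turned to 0.187. The interaction contains the control, the only group given GFP virus, so an effect of Cre virus common to the other 3 groups would also appear in it with the sign opposite to that effect. The MAPK output list has this pattern, with medians of 1.05, 0.81 and 1.06 above the control in oncogene, Wt1-null and double MEFs. By limma 1556 genes had an unadjusted p below the threshold, and the count was 5 without Wt1-null replicate 1. It was 0 without Wt1-null replicate 3, 4 or 5, control replicate 2 or 3 or oncogene replicate 6, 0 with Xist as a covariate, 4 over all probe sets and 2748 with array weights.

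**Figure D3:**
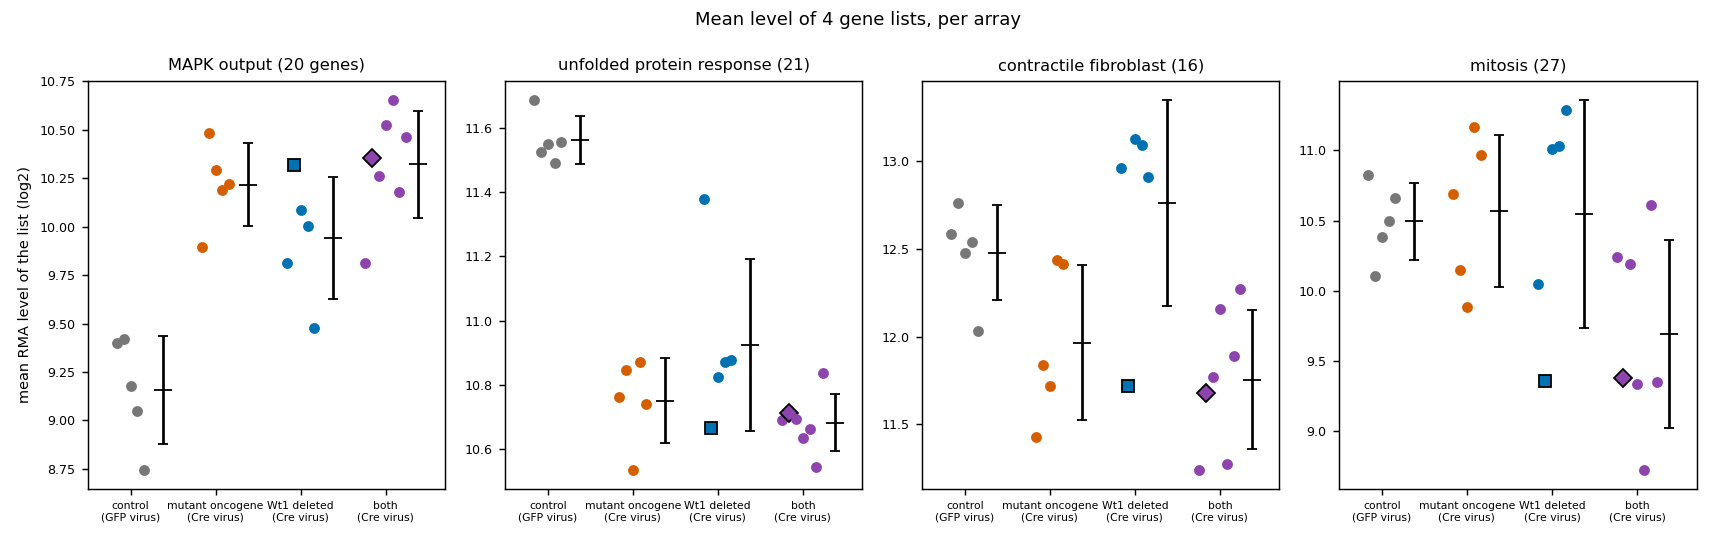
Mean RMA level (log2) over the measured genes of 4 lists in each array, by group, with the mean and SD beside the points. Square and diamond mark Wt1-null replicate 2 and double replicate 2, and the mean of the mitosis list was 10.57 in the oncogene and 9.69 in the double group.

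Across 18193 genes, which are not independent replicates, the oncogene effect in cells with Wt1 and that in Wt1-null cells had a Pearson r of 0.482, with no array shared between them, and 0.493 without Wt1-null replicate 2. The first of these effects, like the Wt1 effect in cells without the oncogene, includes the change from GFP to Cre virus. The Wt1 effect in cells with and without the mutant oncogene had an r of 0.0, and -0.175 without that array. Jackknife standard errors over the arrays were 0.271 and 0.463.

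**Figure D4:**
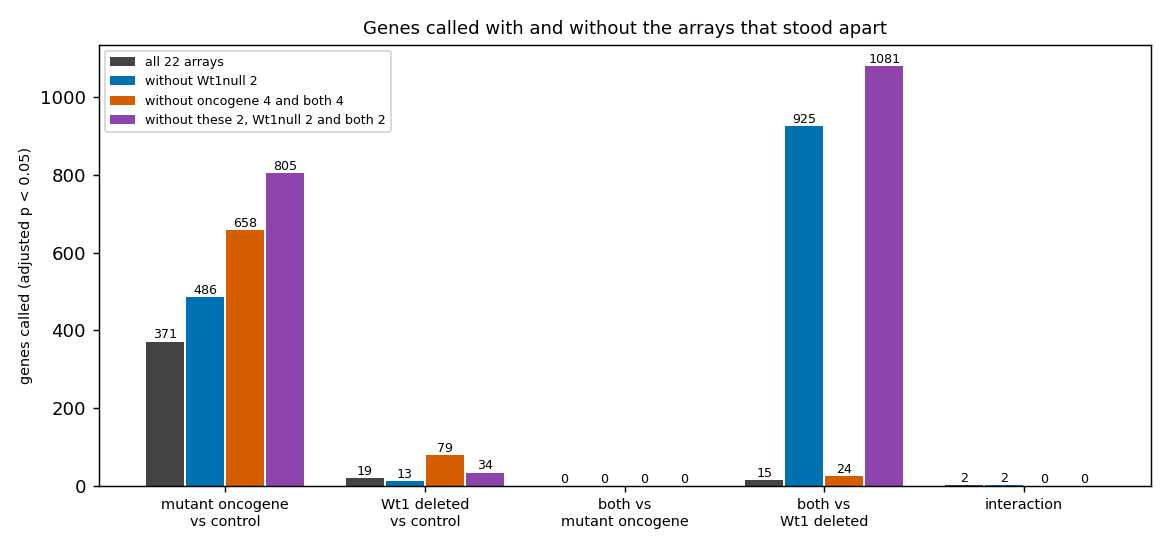
Number of genes called at an adjusted p below 0.05 in each comparison, with all 22 arrays and with arrays that stood apart left out. Double against Wt1-null gave 15 genes with all arrays and 925 without Wt1-null replicate 2, while double against oncogene gave 0 in each setting shown.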

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

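The tests of single arrays and of explanations in this part were chosen after the results were seen, while the interaction and its list tests were planned. Of 248 sets of values, each a named gene or a passing list within 1 group, 29 held an array far from the others, against 12.4 by chance at 1 in 20. Wt1-null replicate 2 held 8 of them. It read 12.57 for Slc14a1, 13.51 for Agtr2, 10.90 for Bmp2, 10.39 for Cd34, 11.52 for Serping1 and 13.27 for Mmp3, all above the other Wt1-null arrays. Its means of the contractile fibroblast list (11.72) and the cholesterol synthesis list (10.38) were below them.

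Wt1-null replicate 2 may be a mislabelled sample, or may share its RNA with double replicate 2. The SD of their difference was 0.152, and the smallest of the other pairs from different groups had 0.285. A score over genes called in a fit of oncogene and control arrays alone was 0.55 in it, against -1.31 to -0.63 in the other Wt1-null arrays and -0.43 to 0.98 in arrays labelled with the mutant oncogene. Being in the same set of accessions is not the cause, since the closest array of its own set had an SD of 0.351, but shared handling was not tested. A wrong genotype, a wrong label and shared material stay open, and no biological explanation was tested.

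Trib3 (3.46) and Car6 (2.09) had an interaction, although additive falls would have reached background at both. They belong to 13 genes called lower than the control in all 3 groups given Cre virus, with Chac1, Aldh1l2, Pck2, Artn, Acot2, Slc6a9, Slc7a3, Gpt2, Echdc2, Derl2 and Ddrgk1. Over these 13 the median change was -1.64 in oncogene, -1.65 in Wt1-null and -1.75 in double MEFs. The median interaction was 1.63, positive at all 13. Choosing genes low in all 3 groups does not fix this sign, since additive falls would give no interaction. The choice used the same control arrays, so it may still favour a positive value. The set of accessions does not explain them, since the median change was -1.65 within the set of 4 oncogene and 4 control arrays, where none of the 13 overlapped, and -1.58 for 7 double and 4 control arrays, where 10 of 13 did not overlap. Cre virus in place of GFP virus also stays open. Oncogene and Wt1-null arrays differed by a median of 0.20, a small difference that the choice of genes may favour, and virus and genotype cannot be told apart.

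The mitosis list (interaction -0.93) and the DNA replication list (-0.57) had lower medians in double MEFs than in the other groups, but neither passed with an estimated correlation (interaction adjusted p = 0.386 and 0.415, double against control 0.564 and 0.694, by camera), and no mitosis gene was called. The difference in mitosis between double and oncogene arrays was -0.88, and -0.991 with an exact permutation p = 0.0476 without oncogene replicate 4 and double replicate 4, which argues against those 2 arrays as the cause, and -0.917 with an exact permutation p = 0.0794 without the near-identical pair as well. Among arrays low in Xist it was -0.806 with an exact permutation p = 0.238 for 2 double and 5 oncogene arrays, where 0.048 was the smallest p possible. Within the accession set of 7 double and 4 oncogene arrays it was -0.85, about as large as with all arrays. A difference of this size inside 1 set argues against the set of accessions as its source. The exact permutation p = 0.0758 within that set leaves chance open. The sex of the embryos cannot be told apart from the groups with 2 double arrays low in Xist, and loss of Wt1 together with the mutant oncogene may also be the source.

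Other lists passed in the interaction at the preset correlation and none with an estimated one (adjusted p = 0.0917 for MAPK output and 0.386 to 0.415 for the rest, by camera). Their medians were -0.71 (MAPK output), -0.20 (secreted factors of senescence), -0.24 (fibrillar matrix), -0.50 (contractile fibroblast), -0.075 (reported WT1 targets), 0.39 (NRF2 targets), -0.64 (immediate early) and 0.20 (unfolded protein response). Double replicate 4 stood apart for Slc14a1 (10.06), Trib3 (8.06) and Slc6a9 (9.68). Wt1-null replicate 1 did so for Car6 (6.57) and Pck2 (11.83), and Wt1-null replicate 5 for Cdsn (9.79), Nudt6 (9.93), fibrillar matrix (13.24) and immediate early genes (10.43). Control replicate 1 stood apart for Lss (10.80), Pom121 (9.93) and cholesterol synthesis (11.18), and oncogene replicate 1 for Artn (7.68) and cholesterol synthesis (10.91). The remaining values were oncogene replicate 4 for secreted factors of senescence (7.88), oncogene replicate 5 for Igfbp6 (10.52), double replicate 1 for Igf1r (9.27) and NRF2 targets (11.08), double replicate 3 for Sod3 (6.50) and sex-linked genes (7.67), and double replicate 6 for Col6a3 (13.90).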

How the results depend on the processing

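The fits without pairs of arrays, with averaged arrays, with Xist as a covariate and within 1 accession set were chosen after the results were seen. Each comparison with the control is also a comparison of Cre with GFP virus, part of the sets of accessions follows the groups, and the number of arrays is small, so the counts moved with single arrays. Genes called between oncogene and control arrays ranged from 139 to 683 with 1 array left out, between Wt1-null and control from 2 to 121, between double and Wt1-null from 0 to 925, and in the interaction from 0 to 5. Without oncogene replicate 4 and double replicate 4 these were 658, 79, 24 and 0, and without Wt1-null replicate 2 and double replicate 2 they were 454, 5, 671 and 0. Without all 4 arrays they were 805, 34, 1081 and 0. With array weights they were 4417, 6016, 3501 and 2748, where Wt1-null replicates 3 and 4, which are nearly alike, had weights of 3.35 and 3.42, and with these 2 averaged the counts were 301, 3, 0 and 0.

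A fit of only the groups compared called 770 genes for oncogene against control, 599 for Wt1-null against control and 0 for double against Wt1-null. An added limit of 1 on the log2 change left 201, 15 and 9. Accession set as a fixed block gave 514, 3 and 0, with 3 in the interaction, and as a random block 449, 5 and 0, with 1 in the interaction. Within accession set 2 alone, 0 genes were called for Wt1-null against control. For double against Wt1-null, the mean of all probe sets gave 6, every probe set 3, median-centred arrays 9, Xist as a covariate 1 and the replicate block 0. For the interaction, every probe set gave 4, leaving out dim genes 1, the replicate block 1 and Xist as a covariate 0. Of 42 list results, 3 passed with an estimated correlation and 7 with fry.

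Directions turned at a few places. Other probe sets gave -0.062 for E2f2 and -0.101 for Egr3 in oncogene against control. Between double and oncogene arrays the sex-linked list turned by the camera direction, with a median of -0.065 without dim genes, and the median of the contractile fibroblast list was 0.081 with Xist as a covariate. The p53 target list had -0.057 with accession set as a fixed block, -0.204 within set 2 and -0.046 without Wt1-null replicate 2 in Wt1-null against control, where fibrillar matrix had -0.066 without Wt1-null replicate 5 and -0.031 within set 2. DNA replication had -0.084 with the replicate block in oncogene against control, and the secreted factors of senescence had an interaction of 0.187 with the fixed block. The cause was not tested for these shifts.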

Other observations

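The tests in this part were chosen after the results were seen, apart from the comparisons of the design. Double against control MEFs, a comparison outside the design, gave 1078 called genes, 633 higher and 445 lower. Slc14a1, Agtr2, Mmp3 and Bmp2 were higher by 4.47, 4.17, 4.08 and 3.94, and Gjb2 and Cnn1 lower by a log2 change of -4.04 and -2.71. All 20 MAPK output genes were higher (median 1.06, 12 called) and 18 of 21 unfolded protein response genes lower (12 called), with an adjusted p = 0.00297 for both with an estimated correlation. Of 16 cholesterol synthesis genes 9 were called, all lower (median -0.99, adjusted p = 0.0906 with an estimated correlation).

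Oncogene against Wt1-null MEFs, which all received Cre virus, gave 3 genes with all arrays: Sema5a, Dlk1 and Igfbp6, higher by 3.14, 2.56 and 0.99. Without Wt1-null replicate 2 it gave 193, 116 higher and 77 lower. Slc14a1, Agtr2, Bmp2 and Cd34 were then higher by 5.14, 4.80, 3.97 and 3.49, while Trib3, Chac1 and Car6 were not among the 8 largest changes either way. All 16 contractile fibroblast genes were lower (median -0.90, 4 called, adjusted p = 0.0552 with an estimated correlation).

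Other splits of the arrays were counted for each comparison, 100 splits each with the real one included. For oncogene against control 1 split gave 371 genes or more, and the highest of the others gave 27. For Wt1-null against control 1 gave 19 or more and the highest other gave 1. Residuals dealt to unchanged groups gave a mean of 1.44 calls in that comparison over 100 draws, with 144 in the highest. For double against Wt1-null 3 splits gave 15 or more, with a highest other of 517. That split moved Wt1-null replicate 2 into the double group and double replicate 3 out of it. Without Wt1-null replicate 2 1 split gave 925 or more, and the highest other gave 513. For the interaction, with residuals of an additive model dealt again, 3 of 100 gave 2 genes or more, the highest being 227. Chance is an unlikely source of the count for oncogene against control. For Wt1-null against control the splits make it unlikely, but an unchanged draw passed 19. The count without Wt1-null replicate 2 is left open, since that array was singled out for its likeness to the double group and the splits did not repeat that choice. Fewer than 5 of 100 splits reached the count with all arrays and that of the interaction, although single splits went far above them. For double against oncogene the test was void, since the real count was 0 and 100 of 100 splits gave 0 or more by construction. The highest split gave 1759, which points to a structure of the arrays other than the groups, as does the 227 above. What this structure follows was not tested. The split with 517 moved Wt1-null replicate 2 into the double group, which it resembled, so that count may follow the groups.

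Chance could not be excluded for the number of lists passing with the preset correlation. It was 6 for oncogene against control, which 61 of 100 splits reached (highest other 13), 9 for Wt1-null against control (30 of 100, highest 13), 8 for double against oncogene (36, highest 14), and 9 for double against Wt1-null (20, highest 12). It was 10 for the last comparison without Wt1-null replicate 2 (12, highest 14) and 10 for the interaction (10, highest 14). A correlation of oncogene effects of 0.482 or more came from 6 of 100 splits (highest 0.635), and one of Wt1 effects of 0.0 or more from 43 (highest 0.679).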
